A study of Triticum aestivum with 45 samples.

How the data were processed

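The series holds RNA-seq libraries from spikelets of hexaploid bread wheat (Triticum aestivum). Spikes of 3 genotypes were sprayed at anthesis with water, methyl jasmonate (MeJA), salicylic acid (SA) or ethephon, a compound that releases ethylene, each hormone at 100 µM. Spikelets were taken at 0 h from unsprayed spikes and at 8 h from sprayed spikes. The genotypes were the spring wheat cultivar Superb and the doubled haploid lines GS-1-EM0040 (DH1) and GS-1-EM0168 (DH2), which the labels describe as derived from the donors CIMMYT11 and CM82036, with Superb as the recurrent parent. This gave 15 groups of 3 libraries, 45 in all, and the group of each library was read from its genotype and treatment labels.

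The deposited values are raw read counts per gene, 1 column per library, with no scaling applied by the authors as far as the values show: they are whole numbers and each library has a different total. Reads were aligned with STAR 2.5.3a, per the submitters' processing notes, which also name DESeq2 without stating its role. The program that counted the reads, the handling of reads that map to several places and the strand setting are not given in the sources used here. The table lists 110790 gene identifiers in the style of the IWGSC RefSeq v1.0 annotation, and 17811 of them had no count in any library. Every row carried a gene identifier. Homoeologous and duplicated wheat genes may share reads, so the count of a single copy is less certain than that of the whole family.

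The files do not pair gene identifiers with names, and 0 of the identifiers matched the reference table used here, which belongs to another assembly (IWGSC CS RefSeq v2.1). Genes are therefore given by identifier only, with at most 2 that rose and 2 that fell per comparison, and gene lists fixed beforehand were not used here. The chromosome and the order of genes along it were read from the identifiers.

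Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr over the 15 groups, which left 63091 genes holding 99.73% of all counts. Libraries were scaled by TMM. A quasi-likelihood model with a mean per group was fitted to all 45 libraries (glmQLFit, legacy = FALSE), with 30 residual degrees of freedom, and contrasts were tested with glmQLFTest. Benjamini-Hochberg adjusted p under 0.05 was the threshold for a call. Each hormone was set against water at 8 h within each genotype, water at 8 h against untreated spikelets at 0 h within each genotype, and each line against Superb over the mean of the 5 conditions. A conserved response is a call in the same direction in all 3 genotypes. Differences in hormone response between genotypes were tested with 2 degrees of freedom per gene. Standard errors were taken as the absolute log2 fold change divided by the square root of F.

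Levels are given as CPM, the unit of edgeR for counts scaled to the library size, with TMM factors, computed from the deposited counts, as mean ± SD over 3 libraries unless another number is given. Counting intervals are exact 95% Poisson intervals over the summed counts of a group, and a count of 0 was given a limit of 3 counts over the summed libraries. Intervals and limits cover counting error only. Library totals ran from 6446374 to 17940396 counts, with a median of 11251553. The 45 pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom between 2.23 and 19.1, so no library was taken as a duplicate. The labels give 5 plants per treatment group for the sprayed groups, and no number for the untreated ones. They do not say whether replicates came from separate plants, and p-values then measure only the spread between these samples, which may be technical.

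The share of counts in a MeJA-induced set was computed with the set defined in the other 2 genotypes (called up with a log2 fold change of at least 1 in both), and tested by exact two-sided permutation of libraries within genotypes. Overlaps between hormones, which share the water libraries, were set beside a simulation of unchanged groups and beside the overlap of independent lists. Chromosomes were compared by Fisher's exact test, and windows of 100 tested genes by the hypergeometric distribution, with Benjamini-Hochberg adjustment.

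The steps were tested on simulated data for the 63091 genes with 200 changed genes per genotype in the MeJA libraries. At adjusted p under 0.05, 33% of the 2-fold changes and 78% of the 4-fold changes were recovered in Superb, 40% and 80% in DH1, and 45% and 83% in DH2. False calls were 6 of 117, 6 of 126 and 8 of 136. A planted window was found with 0 false windows.

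Named genes were chosen by a rule written before the data were examined. For MeJA and for water against untreated, they have the highest and lowest mean log2 fold changes among genes called in all 3 genotypes with a mean log2 CPM of at least 1. For SA and ethephon, with fewer than 10 conserved calls, they have the highest and lowest fold changes among calls in each genotype. For the lines the same minimum of log2 CPM held, and for differences between genotypes the smallest p. The alternatives tried were DESeq2 size factors, no filter on low counts, a replicate block within genotypes and, for the lines and differences between genotypes, across them (chosen after seeing the data), the Wald test of DESeq2 1.42.0, a minimum absolute log2 fold change of 1, only the 15 libraries of a genotype, untreated libraries only, and leaving out each library. Figures were drawn with matplotlib 3.10.9.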

Results

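RNA was measured in spikelets of 3 wheat genotypes before treatment and 8 h after spraying with water, MeJA, SA or ethephon. MeJA is the methyl ester of the wound and defence hormone jasmonic acid, SA is a hormone of defence against pathogens, and ethephon releases the hormone ethylene. Each of the 15 groups held 3 libraries, and totals ran from 6446374 to 17940396 counts per library. The comparisons ask which genes respond to each hormone within 8 h, and how far Superb and the related lines DH1 and DH2 share the response.

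On the first principal component of log2 CPM, with 39.2% of the variance of the 5000 most variable genes, MeJA libraries of all genotypes lay between 63.2 and 149.3. Superb ethephon replicate 1 lay at 45.7, and the other 35 libraries lay at 10.9 or below. The second component, with 21.4%, set the untreated libraries, all at -55.4 or below, apart from the water libraries, all at 6.9 or above.

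**Figure D1:**
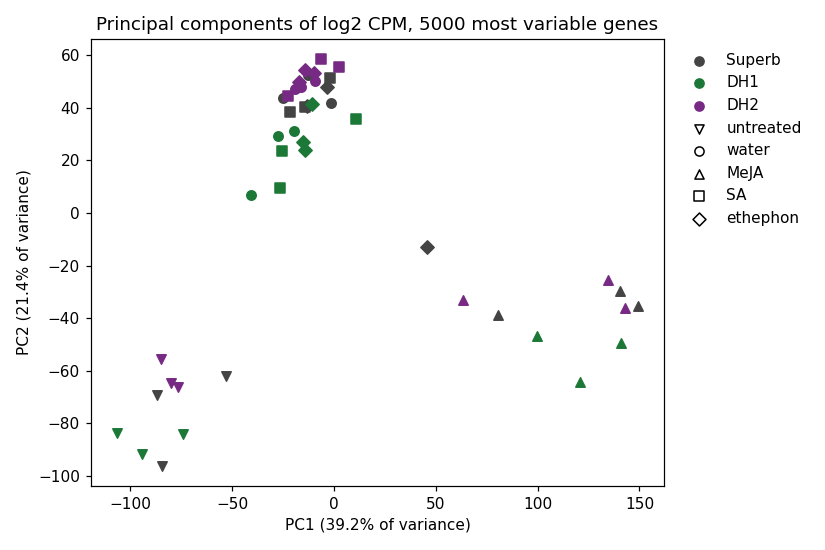
Scores of the 45 libraries on the first and second principal components of log2 CPM (percent of variance on the axes), with colour for genotype and symbol for condition. MeJA libraries lie on the right, from 63.2 upward on PC1, and Superb ethephon replicate 1 lies at 45.7.

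MeJA changed more genes than SA or ethephon in each genotype. TraesCS2B01G555400 on 2B rose from 0.397 ± 0.531 CPM after water to 735 ± 165 CPM after MeJA in Superb (n = 3 each), from 0.25 ± 0.164 to 599 ± 212 CPM in DH1 and from 0.568 ± 0.34 to 1070 ± 95.1 CPM in DH2. Its log2 fold changes of 10.88 (SE 1.52), 11.30 (SE 1.57) and 10.75 (SE 1.42) had adjusted p of at most 1.14e-06 in edgeR's quasi-likelihood test. TraesCS5B01G006500 on 5B rose from 0.106, 0.163 and 0.148 CPM to 224 ± 62.7, 186 ± 77.3 and 276 ± 170 CPM in Superb, DH1 and DH2, with an adjusted p of at most 4.5e-09. Its 3 counts after water in Superb give a 95% counting interval of 0.021 to 0.3 CPM. TraesCS5B01G539900 fell from 12.8 ± 0.842 to 0.565 ± 0.417 CPM in Superb, from 8.61 ± 2.29 to 0.156 ± 0.163 CPM in DH1 and from 7.37 ± 1.87 to 0.16 ± 0.104 CPM in DH2. TraesCS5D01G176400 fell from 9.96 ± 2.11 to 0.543 ± 0.496 CPM, from 7.46 ± 3.6 to 0.132 ± 0.171 CPM and from 6.64 ± 2.07 to 0.251 ± 0.212 CPM in the same order, with an adjusted p of at most 7.49e-07. For these 4 genes all 3 MeJA libraries of each genotype lay on 1 side of its 3 water libraries.

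In Superb 7884 genes rose and 6047 fell after MeJA, in DH1 10300 rose and 7191 fell, and in DH2 9028 rose and 5814 fell. The median log2 fold change of the genes that rose was 1.20, 1.22 and 1.10, and that of the genes that fell was -0.91, -0.84 and -0.87. Changes of at least 1 on the log2 scale were fewer, at 7303, 8875 and 7333 genes.

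The response to MeJA was shared between genotypes. Of 23107 genes called in any genotype, 6039 rose in all 3, against 184 expected from independent lists, and 3126 fell in all 3, against 63.5 expected. Only 15 genes were called in opposite directions in different genotypes. Across genes, which are not independent replicates, log2 fold changes correlated with r = 0.84 between Superb and DH1, 0.86 between Superb and DH2 and 0.82 between DH1 and DH2. These 3 comparisons share no library, but libraries of different genotypes with the same replicate number deviated together within a condition (mean r = 0.44 after MeJA), so the genotypes are not independent repeats. A group of 32 genes lay below 0.1 CPM after water and at 5 CPM or more after MeJA in all 3 genotypes, and 0 genes went the other way. Among tested genes of the A, B and D subgenomes, 9.16%, 9.58% and 10% rose in all 3 genotypes and 5.01%, 4.76% and 5.09% fell.

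The genes induced by MeJA came to hold a large part of the transcriptome. The set defined in DH1 and DH2 took 4.68 ± 0.51% of Superb counts after water and 18.5 ± 4.6% after MeJA (SD, n = 3). With sets defined likewise, the share went from 4.15 ± 0.3% to 15%, 20.1% and 18.6% in the MeJA libraries of DH1 and from 4.71 ± 0.14% to 18.1 ± 4.2% in DH2, a ratio of 3.97 over the genotypes (exact stratified permutation test over 8000 splits, two-sided p = 0.00025, the smallest they can give). With libraries split by replicate number in the same way in all genotypes, the exact two-sided permutation p was 0.1, the smallest that 20 splits can give. The set repressed by MeJA fell from 4.56 ± 0.095% to 1.24 ± 0.39% in Superb, from 4.19 ± 0.28% to 1.18 ± 0.11% in DH1 and from 6.92 ± 0.33% to 2.55 ± 1.1% in DH2. MeJA replicate 1 had the lowest share of the induced set in each genotype, and Superb ethephon replicate 1 stood at 8.08%, while its other ethephon libraries stood at 4.93% and 4.75%. Their 95% Wilson intervals ran from 8.067 to 8.095%, from 4.913 to 4.938% and from 4.739 to 4.771%.

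**Figure D2:**
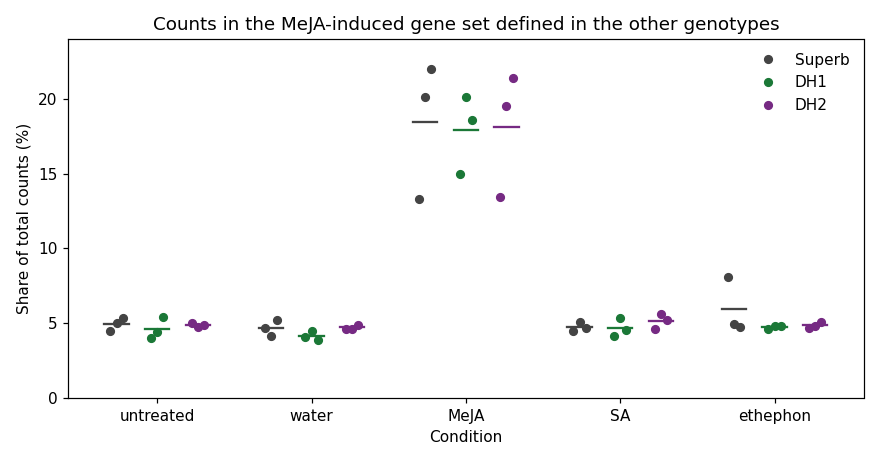
Percent of the total counts of each library that fell in the set of genes induced by MeJA in the other genotypes, by condition, with 1 point per library and a line at the mean of 3. MeJA libraries lie at 13.3% or above, and Superb ethephon replicate 1 at 8.08%.

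SA changed few genes, and nearly all of them rose. In Superb, TraesCS1A01G232500 rose from 0.207 ± 0.181 to 2.8 ± 1.7 CPM (log2 fold change 3.61, SE 0.69, edgeR adjusted p = 0.0177) and TraesCS5D01G550100 from 0.329 ± 0.3 to 3.64 ± 1.54 CPM (3.43, SE 0.60, adjusted p = 0.012). In DH1, TraesCS1D01G233900 had 0 counts in the 3 water libraries, which allows up to 0.084 CPM, and 0.817 ± 0.0636 CPM after SA, at least 9.56-fold higher (adjusted p = 0.00895). Against the same water libraries it stood at 0.791 ± 0.504 CPM after MeJA (adjusted p = 6.75e-05) and at 0.336 ± 0.0554 CPM after ethephon (adjusted p = 0.374). TraesCS2B01G289700 had 1 count after water (0.0334 CPM, 95% interval 0.00071 to 0.16) and 1.5 ± 0.438 CPM after SA. TraesCS7D01G224700, the only gene that fell, went from 15.7 ± 1.72 to 10.6 ± 0.717 CPM (log2 fold change -0.57, SE 0.11, adjusted p = 0.0155). In DH1 its log2 fold change was -0.32 after MeJA (adjusted p = 0.025) and -0.39 after ethephon (adjusted p = 0.374), and it stood at 12.6 ± 1.45 and 12.8 ± 0.173 CPM after water in Superb and DH2. In DH2, TraesCS5D01G311900 rose from 0.214 ± 0.135 to 2.87 ± 0.867 CPM (3.64, SE 0.64, adjusted p = 0.00374), and TraesCS2A01G468200 stood at 4.16, 1.33 and 0 CPM in the SA libraries, with 1 count after water (adjusted p = 0.0245). For the other 6 genes, all 3 SA libraries lay on 1 side of the 3 water libraries, as 1 of 10 splits would by chance. Single libraries ended most of these calls. TraesCS1A01G232500 was not called without Superb SA replicate 3 or any Superb water library, nor by DESeq2. TraesCS5D01G550100 was not called without Superb SA replicates 1 or 2 or water replicates 2 or 3, nor by DESeq2. TraesCS1D01G233900 was not called without DH1 water replicates 2 or 3, and TraesCS7D01G224700 without these or DH1 SA replicates 1 or 3, nor with no filter on low counts. TraesCS5D01G311900 was not called without DH2 water replicate 1 nor by DESeq2, and TraesCS2A01G468200 without DH2 SA replicate 1 or any DH2 water library, nor by DESeq2. The call of TraesCS2B01G289700 stood without each of the 6 DH1 libraries, by DESeq2 and with no filter.

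The counts after SA were 13 genes up and 0 down in Superb, 65 up and 1 down in DH1, and 31 up and 0 down in DH2. At an unadjusted p under 0.05 they were 1953, 3270 and 2215. With no change at all, a 0.05 share of the 63091 tested genes would lie under it. The counts of Superb and DH2 were below that share, and that of DH1 was close to it. DESeq2 called 19, 110 and 51 genes. In all 3 genotypes 9 genes rose, 2 of them on 5B and 1 each on 1A, 1B, 1D, 2D, 5A, 5D and 7A, against 6.58e-06 expected from independent lists. These 9 fell to 5 and 1 without Superb SA replicates 1 and 3, and to 2, 1 and 0 without Superb water replicates 1, 2 and 3. In Superb 8 and 2 genes were called without SA replicates 1 and 3, and 4, 1 and 0 without water replicates 1, 2 and 3. In DH1 38 and 25 genes were called without water replicates 2 and 3, and in DH2 51, 18 and 11 without SA replicate 1, SA replicate 3 and water replicate 1.

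The named genes that were called higher after ethephon in Superb were high in 1 library. TraesCS4B01G237500 stood at 24.5 CPM in Superb ethephon replicate 1 and at 0.406 and 0 CPM in replicates 2 and 3, with 0 counts after water (edgeR adjusted p = 0.00951 over the 3 libraries). TraesCS1D01G392500 stood at 165 CPM in replicate 1 and at 0.892 and 0.28 CPM in the others, against at most 0.333 CPM after water (adjusted p = 0.0258). TraesCS3A01G307500, the single gene called lower, stood at 0.216, 0.406 and 0.28 CPM in the 3 ethephon libraries, all below the lowest water library at 0.612 CPM (log2 fold change -2.45, SE 0.47, adjusted p = 0.0283). In all, 35 genes were called up and 1 down in Superb, and 30 of these 36 rose after MeJA in all 3 genotypes, against 3.45 expected by chance. Without Superb ethephon replicate 1, edgeR called 0 genes. Without Superb water replicates 1, 2 and 3 it called 0, 6 and 0, of the 3 named genes only TraesCS3A01G307500 without replicate 2, and without ethephon replicates 2 and 3 it called 199 and 143. At an unadjusted p under 0.05 there were 2517 genes, below a 0.05 share of the 63091 tested genes, and DESeq2 called 81.

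In DH1 the only call, TraesCSU01G207700, stood at 65.2, 0.684 and 0 CPM in the ethephon libraries. It was not called without DH1 ethephon replicate 1 or any DH1 water library, while 47 and 15 genes were called without DH1 ethephon replicates 2 and 3. In DH1 4543 genes had an unadjusted p under 0.05, above a 0.05 share of the 63091 tested genes. In DH2 edgeR called 0 genes after ethephon, and DESeq2 called 7. The DH2 count at an unadjusted p under 0.05 was 1305, below that share. Without DH2 water replicates 2 and 3 edgeR called 3 and 5. No gene was called in all 3 genotypes.

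Superb ethephon replicate 1 also carried genes of DH1. The 82 genes expressed in DH1 and at no more than 5% of that level in Superb and DH2 stood at 27.5% of their DH1 level in this library, and at 1.18% to 1.88% in the other 14 Superb libraries. The 93 genes found likewise for DH2 stood at 0.652%, within the range of 0.587% to 1.62% in the other Superb libraries. In DH1 ethephon replicate 1, these DH2-only genes stood at 13.1% of their DH2 level, and at 0.527% to 1.35% in the other DH1 libraries. The percent is taken over the summed level of the set, so a few genes may carry it. TraesCS5D01G559300, at 16.6 CPM in DH2, had 0 counts in all 15 DH1 libraries. TraesCS6D01G392000, at 26.4 CPM in DH2, reached at most 0.148 CPM in DH1. DH2 material mixed in at 13.1% would have raised both, so these values argue against it for these genes. What raised the DH2-only genes there was not tested. The DH1 ethephon counts above and the DH1 ethephon covariance below include this library unless it is named as left out.

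**Figure D3:**
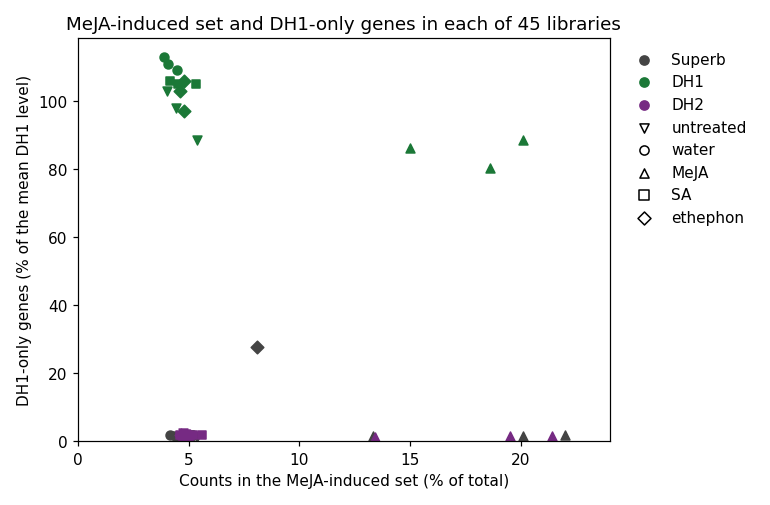
Level of the DH1-only genes, as percent of their mean level in DH1, against the percent of counts in the MeJA-induced set, for each of the 45 libraries, with colour for genotype and symbol for condition. Superb ethephon replicate 1 lies alone at 27.5% and 8.08%.

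The hormones share their water libraries, so overlaps were set beside simulated unchanged groups. In DH1, 17 of the 65 genes raised by SA also rose after MeJA, against 10.6 for independent lists. In Superb and DH2, 0 and 4 did, against 1.62 and 4.44. The simulation gave 0 shared calls in each genotype, but groups without changed genes give few calls to share, so this 0 is no reference. Opposite calls after MeJA and SA were found for 1, 6 and 7 genes in Superb, DH1 and DH2. In Superb, 30 genes rose after both ethephon and MeJA, against 4.37 for independent lists, and these are the calls lost without ethephon replicate 1. The covariance of log2 fold changes of MeJA and SA across 46388 genes was 0.085 in DH1, where the simulated covariance was 0.032. In Superb it was 0.033 with a simulated value of 0.035, and in DH2 0.025 with 0.028. The correlation of MeJA and SA in DH1 was 0.4. Its simulated value of 0.49 is no reference, since the simulated MeJA groups hold no changed genes. MeJA and ethephon in DH1 had a covariance of 0.086, with a simulated value of 0.032, and shared 0 of the calls. For this pair it was 0.096 with 0.035 in Superb, ethephon replicate 1 included, and 0.0077 with 0.028 in DH2. Part of each overlap may come from the shared water libraries.

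Between 0 h and 8 h, spikelets sprayed with water changed about as many genes as MeJA did. TraesCS4D01G298300 rose from 0.261 ± 0.251 to 148 ± 15.3 CPM in Superb, from 1 count (0.0306 CPM, 95% interval 0.00064 to 0.14) to 134 ± 46.5 CPM in DH1 and from 2 counts (0.0743 CPM, 0.007 to 0.21) to 129 ± 9.84 CPM in DH2 (edgeR adjusted p at most 1.64e-16). TraesCS6B01G063900 rose from 0.825, 0.125 and 0.176 CPM to 145 ± 1.74, 155 ± 76 and 119 ± 14.3 CPM in Superb, DH1 and DH2. TraesCS1D01G375000 fell from 71 ± 12.9 to 1.04 ± 0.449 CPM in Superb, from 76.5 ± 26 to 0.629 ± 0.5 CPM in DH1 and from 69.7 ± 34.1 to 1.17 ± 0.393 CPM in DH2. TraesCS6A01G094200 fell from 153 ± 86.3, 134 ± 77.6 and 130 ± 88.9 CPM to 2.46 ± 1.42, 1.75 ± 0.894 and 4.91 ± 2.3 CPM (adjusted p at most 1.04e-06). In Superb 8769 genes rose and 8580 fell, in DH1 8282 and 7913, and in DH2 8154 and 8726. The balance of the directions turned with DESeq2 size factors, with 8424 up and 8925 down in Superb and 7548 up and 8386 down in DH1. With a log2 fold change of at least 1, 3280 rose and 4639 fell in Superb, 2922 and 4438 in DH1, and 3127 and 4486 in DH2. In all 3 genotypes 5121 genes rose and 5268 fell. The contrast holds the spray, the time of day and 8 h of development together, and it cannot part them.

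The named genes, chosen for the largest fold changes, were near 0 in Superb or in a line. TraesCS2D01G147900 stood at 21.1 ± 3.1 CPM in DH1 and 19.2 ± 1.88 CPM in DH2 (n = 15 each), with 2 counts over the 14 Superb libraries other than ethephon replicate 1, where it stood at 6.11 CPM. TraesCS2A01G289400 stood at 15.3 ± 4.94 CPM in DH1 and 7.76 ± 2.22 CPM in DH2, against 0.0275 ± 0.0388 CPM in those 14 libraries and 4.6 CPM in ethephon replicate 1. TraesCS5D01G559300 had 0 counts in the 15 DH1 libraries and 30.7 ± 5.46 CPM in the 14 Superb libraries, so it was at least 1830-fold lower in DH1. TraesCS6D01G392000 had 3 counts in DH1 and 22.5 ± 3.14 CPM in Superb. In DH2, TraesCS5B01G299700 stood at 0.0405 ± 0.0829 CPM and TraesCS5B01G274100 at 0.0179 ± 0.0547 CPM, against 21.3 ± 2.57 and 11.5 ± 1.13 CPM in Superb. Each of these differences had an edgeR adjusted p of at most 1.84e-14.

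In DH1 1600 genes were higher and 1767 lower than in Superb, and in DH2 2742 were higher and 4031 lower. The median log2 fold change of the called genes was 0.67 for those higher and -0.67 for those lower in DH1, and 0.49 and -0.53 in DH2. From the untreated libraries alone the counts were 816 and 803 genes. Without Superb ethephon replicate 1 they were 3699 and 6272.

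The differences lay in blocks along chromosomes. In DH1, 12.4% of the tested genes of 7A, 12.1% of 6A, 10.2% of 6B, 9.27% of 5A, 8.1% of 5D and 6.4% of 7D were called, against 5.34% over all genes (Fisher's exact test, adjusted p at most 0.00986). In DH2 the chromosomes with an excess were 1A with 19.3%, 5B with 15.9%, 3B with 15.1%, 7B with 12.9%, 7A with 12% and 5A with 11.9%, against 10.7% over all genes (adjusted p at most 0.0345). Fisher's test treats genes as independent, which calls in blocks are not, so these p-values may be too small. Among windows of 100 tested genes, and with a log2 fold change of at least 1, 34 of 626 were enriched in DH1 and 48 in DH2. They held 46.8% and 48.9% of such calls on the chromosomes. In DH1 the highest shares were 31% in window 25 of 6B and 29% in window 24 of 6A, both near the end of the identifier order. In DH2 they were 33% in window 32 and 31% in window 22 of 5B, 31.7% in window 33 of 5A and 29% in window 1 of 3B.

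**Figure D4:**
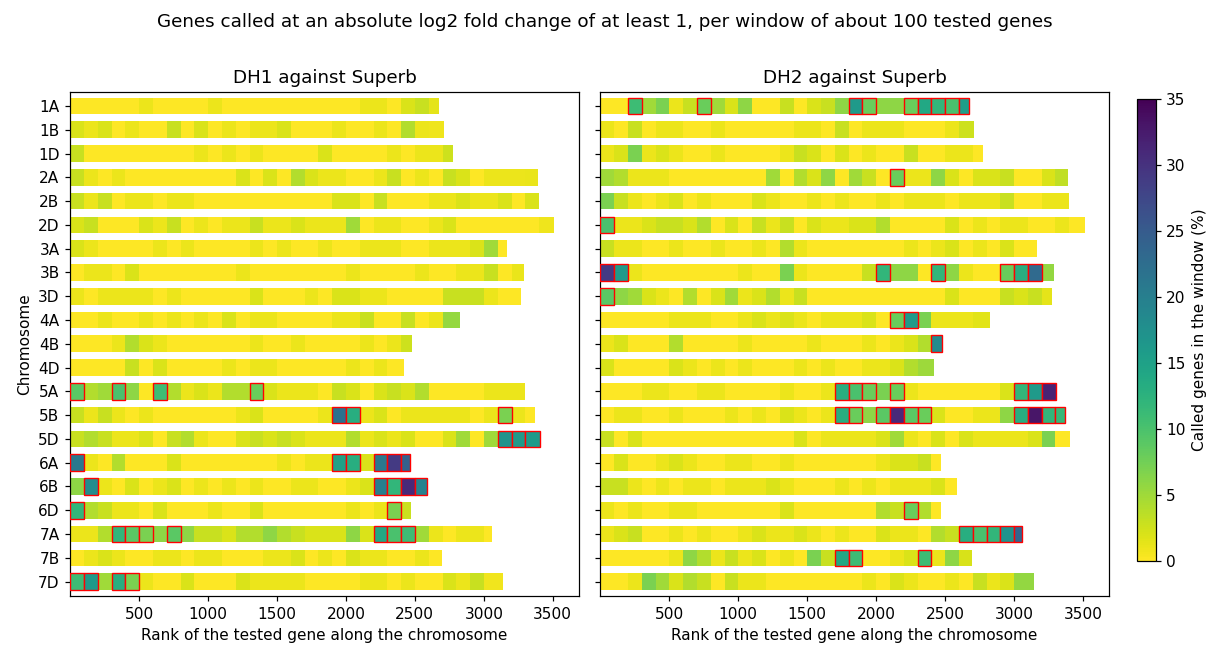
Percent of tested genes called with an absolute log2 fold change of at least 1 in windows of about 100 tested genes, by chromosome and in identifier order, for DH1 and DH2 against Superb. Red outlines mark the 34 and 48 enriched windows, some next to each other and some alone.

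The response to MeJA differed between genotypes at 14 genes by the test of the difference itself. TraesCS5A01G547700 rose from 48.6 ± 11.3 to 488 ± 51.3 CPM in Superb and from 47.6 ± 10.2 to 444 ± 52.4 CPM in DH1, and stood at 29.5 ± 6.64 CPM after water and 36.1 ± 7.8 CPM after MeJA in DH2 (edgeR adjusted p = 2.3e-05 for the difference). TraesCS5B01G515500 rose from 85.8 ± 1.19 to 344 ± 54.3 CPM in DH2, and stood at 101 ± 6.3 and 122 ± 32.3 CPM in Superb and at 87.2 ± 16.7 and 113 ± 13 CPM in DH1 (adjusted p = 2.3e-05). For SA and ethephon edgeR found 0 genes whose response differed between genotypes. At an unadjusted p under 0.05 there were 1066 and 1729, both below a 0.05 share of the 63091 tested genes. DESeq2 was not used for these differences. Ethephon gave 9, 10 and 3 genes without DH1 ethephon replicate 2, Superb ethephon replicate 2 and DH2 water replicate 3, and SA gave 1 without DH2 water replicate 3. The MeJA count was 6 to 9 without each of the 3 DH1 MeJA libraries, the 3 DH1 water libraries, and DH2 MeJA replicates 2 and 3.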

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

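All tests below except that of the difference between genotypes and its relabelling were chosen only after the result was seen. The response to MeJA differed between genotypes at 14 genes by the test of the difference. TraesCS5A01G547700 (F = 41.6) rose in Superb and DH1 by 3.33 and 3.22 on the log2 scale, with a log2 fold change of 0.29 in DH2. TraesCS5B01G515500 (F = 40.6) rose in DH2 by 2.00, with 0.27 in Superb and 0.37 in DH1. Relabelling the genotypes within conditions gave at least 14 genes in 6 of 80 splits, the real one included, with 1152 as the highest other value. By these splits, which ignore replicate number, chance is not excluded for the count of 14. Of the 14 genes, 8 lay in windows enriched for line differences in either line, where 1.74 were expected (one-sided binomial test, p = 8.4e-05). The binomial test treats genes as independent, and the windows were found in the same libraries. With a replicate block across genotypes, chosen after seeing the data, the count was 24. Splits with several times the real count point to a structure of the samples. Same-numbered MeJA libraries deviated together across genotypes (mean r = 0.44), and whether this made those splits was not tested.

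Superb ethephon replicate 1 resembled the MeJA libraries. A swapped label is argued against, since the MeJA-induced set held 8.08% of its counts while the lowest Superb MeJA library held 13.3%. A response of Superb to ethephon is argued against, since the other 2 ethephon libraries reached 4.93% at most and the highest Superb water library 5.18%. DH1-only genes stood at 27.5% of their DH1 level and DH2-only genes at 0.652%, and of 42 candidate libraries DH1 MeJA replicate 1 left the smallest residual, 0.0588 of the deviation at a fraction of 0.316. The fraction was 0.292 (95% interval 0.248 to 0.327) from DH1 markers that do not respond to MeJA. From MeJA-induced genes it was 0.311 (0.306 to 0.317), a difference of 0.019. These intervals come from resampling 71 and 1040 genes within this library. They treat genes as independent and do not cover the choice of the source library. A candidate explanation is material of DH1 MeJA replicate 1 mixed in, at a step these data do not show.

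MeJA replicate 1 responded less than replicates 2 and 3 in each genotype. Its induced genes reached 0.446, 0.648 and 0.362 of the rise in replicates 2 and 3 in Superb, DH1 and DH2, while its repressed genes reached 0.854, 0.974 and 0.731 of the fall. Dilution with RNA of plants without MeJA would give equal fractions, and the smallest difference was 0.326. Low depth is argued against, since replicate 1 was the shallowest MeJA library in 1 of the 3 genotypes. No biological explanation was tested, and a shorter or weaker exposure, or a batch shared by same-numbered MeJA libraries (mean r = 0.44 between genotypes), stays open.

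The line differences concentrated in blocks of neighbouring genes. Random placement is argued against by 34 enriched windows in DH1 and 48 in DH2, where 100 shuffles gave at most 1. Poorer mapping of donor alleles, as the whole cause, would lower most genes in the line, and 48% of the calls in enriched windows were lower in DH1 and 56.9% in DH2. The shares cannot decide on mapping that favours the donor allele at some genes and the Superb allele at others. Such mapping would give calls in both directions. Donor chromosome segments kept in the lines are consistent with these values, as a hypothesis found and tested on the same data.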

How the results depend on the processing

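Leaving out the first MeJA libraries and Superb ethephon replicate 1 for the share, and the test of replicate numbers across genotypes with its block and its splits were chosen only after the result was seen. Of 367 counts under an alternative, 297 stayed within 1.5 times the reported value, 69 moved and 1 was weaker, and of 605 values of named genes 561 stayed the same, 44 were weaker and 0 moved to the other direction. All 20 counts stayed within 1.5 times with DESeq2 size factors, which moved the median gene by at most 0.027 on the log2 scale. Leaving out the first MeJA library of each genotype moved none of 5 counts by that much. The cause of the changes below was not tested except where a stricter threshold or fewer libraries set them.

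With a minimum absolute log2 fold change of 1, MeJA gave 7303, 8875 and 7333 genes in Superb, DH1 and DH2 and 4973 conserved genes, water against untreated 7919, 7360 and 7613, and the lines 1047 and 1314. With untreated libraries only, DH1 and DH2 gave 816 and 803. The DESeq2 Wald test gave 110 genes for SA in DH1 and 51 in DH2, and 81, 10 and 7 for ethephon in Superb, DH1 and DH2. With only the 15 libraries of the genotype, SA gave 4 genes in Superb, 14 in DH2 and 2 conserved, and ethephon 0 in Superb and 0 in DH1. With no filter on low counts, ethephon gave 11 genes in DH1.

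Within genotypes, 10 of 36 same-numbered pairs (hormone or untreated with water) had deviations correlated above 0.1 (range -0.38 to 0.39), and 24 of 45 libraries, not all, correlated best with their own number, where 15 would by chance. Across genotypes within a condition, 38 of 45 pairs lay above 0.1 (range -0.2 to 0.68) and 39 of 45 libraries correlated best with their own number. The mean r was 0.29, 0.24, 0.44 and 0.28 in untreated, water, MeJA and SA libraries, the highest of 36 matchings in each (exact one-sided permutation p = 0.0278), and 0.09 after ethephon (p = 0.167). The labels do not say what a number stands for, so this is a hint from the data, not the design. With a replicate block within genotypes, ethephon gave 2 genes in Superb and 0 in DH1, and ethephon by genotype 2, and no other count moved by over 1.5 times. Of the named genes, TraesCS2A01G468200 after SA and TraesCS4B01G237500, TraesCS1D01G392500, TraesCS3A01G307500 and TraesCSU01G207700 after ethephon were not called with this block. With a replicate block across genotypes, DH1 and DH2 gave 5674 and 9829 genes, MeJA by genotype 24, SA by genotype 0 and ethephon by genotype 2.

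Leaving out 1 library at a time, SA gave 0 to 10 genes in Superb, 25 to 68 in DH1, 51 at most and 11 at least in DH2, and 0 to 10 conserved. Ethephon gave 0 to 199 in Superb, 0 to 47 in DH1 and 0 to 5 in DH2. MeJA by genotype gave 6 to 16, SA by genotype 0 to 1 and ethephon by genotype 0 to 10. SA conserved fell to 5 and 1 without Superb SA replicates 1 and 3, and to 2, 1 and 0 without Superb water replicates 1, 2 and 3. The share of counts in the MeJA-induced set after ethephon rose by 0.177 on the log2 scale (exact permutation p = 0.0228), and by 0.0953 (p = 0.059) without Superb ethephon replicate 1, with p = 0.1 for all libraries split by number in the same way in all genotypes. At this depth, 33% to 45% of 2-fold changes simulated in the MeJA libraries were recovered, and recovery after SA and ethephon was not simulated. The planned tests of gene lists were not run.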

Other observations

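Of the tests below, only that of the change between 0 h and 8 h was chosen after the result was seen. Genes induced by MeJA in all 3 genotypes lay side by side more often than shuffled calls. In identifier order along the chromosomes, 57 runs of at least 4 neighbouring tested genes were induced, where 100 shuffles within chromosomes gave 5.02 on average and 12 at most. The longest run held 8 genes on 4B, and runs of 7 lay on 1A, 2A, 2B, 5B and, at 2 places, 7B. Of the genes repressed in all 3 genotypes, 3 runs were found, where the shuffles gave 0.38 on average and 3 at most. This suggests, as a hypothesis, that part of the response to MeJA involves clusters of related neighbours. Reads shared between tandem copies may lengthen such runs, which was not tested.

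The 9 genes raised by SA in all 3 genotypes were not raised by MeJA in all 3. Of 26 genes raised by SA in at least 2 genotypes, 3 rose and 2 fell after MeJA in all 3 genotypes. Among all 63091 tested genes, 6039 rose and 3126 fell after MeJA in all 3. The counts among genes raised by SA lie near these shares, so they show no separation of the hormones. In the first window of 3B, 29 of 100 tested genes were called in DH2 with an absolute log2 fold change of at least 1. Of these, 17 were higher and 12 lower than in Superb. Windows of 5B and 5A held higher shares in DH2, up to 33% and 31.7%. CM82036, the donor of DH2, is known as a source of resistance to Fusarium head blight. Whether the genes of this 3B window take part in it was not tested.

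The principal components raised the hypothesis that MeJA moves genes against the change between 0 h and 8 h. Across genes, the 8 h change of a genotype and the MeJA response of another, which share no library, correlated with r between -0.1 and 0.014 over 6 pairings. The highest, 0.014, goes against a general opposite movement. Among called genes, 1800 rose with time in Superb and fell after MeJA in DH1 where independent lists would give 999, and 1289 rose in both where they would give 1430. Of the genes that fell with time, 1848 rose after MeJA where 1400 would, and 1489 fell where 978 would. Each of the 6 pairings went the same way, and only the genes that rose in both were fewer than independent lists would give. Genes with high counts may be easier to call in both comparisons, which independent lists leave out. The excesses may therefore be too large, and no conclusion is drawn from them.

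Splits of the same libraries were counted for each comparison. For a hormone against water, or water against untreated, 3 libraries against 3 make 10 splits, too few for a share under 0.05. After MeJA the real counts of 13931, 17491 and 14842 genes in Superb, DH1 and DH2 stood beside 1172, 1 and 4009 as the highest of the others, with 1 split as high in each. After SA the real counts of 13, 66 and 31 stood beside 0, 45 and 2, again with 1 split. After ethephon the 36, 1 and 0 genes stood beside 92, 5 and 3, with 2, 9 and 10 splits as high, and the split with 92 genes in Superb points to a structure of its samples. For water against untreated, 17349, 16195 and 16880 stood beside 4, 10 and 108, with 1 split each.

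Of 100 splits, which treat the genotypes as independent, only the real one (1 split) gave 9165 conserved genes after MeJA, the highest other giving 7, and only the real one gave 9 after SA, the others giving 0. Same-numbered libraries of different genotypes deviated together, and splits made in the same way in all genotypes are too few for a share under 0.05. The 9 genes after SA fell to 0 without Superb water replicate 3, to 1 without Superb water replicate 2 or Superb SA replicate 3, to 2 without Superb water replicate 1 and to 5 without Superb SA replicate 1. For ethephon all 100 gave 0. Of 80 relabellings of the genotypes, 1, the real one, gave 3367 genes for DH1 and 6773 for DH2, with 103 and 2 as the highest others. At 1 of 80, this argues against a random grouping of these libraries. The relabellings ignore replicate number and cannot tell chance differences between plants apart from a difference between lines. For differences between genotypes after SA and ethephon the real counts were 0, all 80 splits gave as many, and the highest others were 22 and 15.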
